A study of Mus musculus with 2 samples.

How the data were processed

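RNA was measured in 2 samples of TR1 cells (type 1 regulatory T cells, IL-10-producing CD4 T cells) taken from the small intestine of mice that had received anti-CD3 antibody. One sample came from mice with an intact IL-10 receptor alpha chain and is called wildtype here. The other came from mice carrying the CD4-DNIL-10R transgene and is called impaired. Per the labels' protocols, 15 μg of antibody was injected into the peritoneum 2 times on alternate days, and cells were taken 4 or 48 hours after the last injection. The labels do not say which of the 2 times applies to which sample. They also do not say how many mice were pooled, or how the cells were sorted.

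Per the labels' protocols, RNA was extracted with TRIzol LS, reverse transcribed from an oligo(dT) primer and labelled with biotin for an Affymetrix array. Per the submitters' processing notes, the values were made with affy and RMA, which corrects the background, makes the probe distributions of the arrays equal and summarises probes into probe sets. Versions, genome build and annotation are not given in the sources used here. The deposited table holds log2 values for 34760 probe sets, ranging from 3.86 to 14.6 in the wildtype sample and from 3.84 to 14.7 in the impaired sample, with medians of 6.89 and 6.92. These ranges fit RMA output on the log2 scale without centring per gene, and higher values mean brighter probe sets. Scanner files were not used here, so neither the background correction nor the normalization by the authors could be varied, and no detection call was at hand. RMA compresses folds at low signal, because dim probe sets keep part of their background.

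Probe sets were named through GEO's annotation of the array platform. Of the 34760 probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 were not listed. Only those with 1 symbol were used for genes. Of these, 21553 matched a gene in a RefSeq table of GRCm38.p6 by Entrez identifier, which changed 0 symbols. A gene with several probe sets, as 954 of the 19937 genes had, was represented by the one with the highest mean of both samples. Genes were kept when the brighter sample lay at or above 6.91, the median over all probe sets of the mean of both samples, which left 11124 genes. Genomic coordinates are not given, since no build is named for the table.

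With 1 array per genotype there was no replicate error, and no test of the genotype was possible. No p-value, standard error or count of significant genes is therefore given. The log2 difference (impaired minus wildtype) was used as it stands, and genes were counted by a rule of size, a difference of at least 1 (2-fold). For gene lists, the median difference of the members was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile, if it had at least 5 members past the floor. This describes these 2 arrays and not the genotypes. Of 43 lists fixed before the data were examined, 40 had enough members, and lists of independently drawn genes would put about 2 of the 40 outside these bounds. Members of a real list vary together and some lists share members, so more than that can lie outside without any effect of genotype. The lists hold 825 genes, of which 732 had a value. The number of arrays limits the precision of every value.

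The genes named in the text were set by a rule fixed before the data were examined. It takes the 15 largest and 15 smallest differences among genes past the floor, leaving out symbols of predicted or unnamed genes, and up to 4 members with the largest absolute difference from each list. It also takes Il10ra, Il10rb, Il10, Il17a, Ifng, Foxp3 and Lag3. Genes named outside this rule are marked as chosen after their values were seen.

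The scripts were tested on simulated data built from the 11124 genes of this comparison, with single-gene noise of 0.253 (the scaled median absolute deviation of the measured differences). The 2-fold rule found 4.0% of genes planted with a 1.5-fold change, 50.0% at 2-fold, 96.0% at 3-fold and 100.0% at 4-fold, with 50 genes at each size. It took in 0 of 10924 unchanged genes. The simulated noise was normal, equal at all expression levels and independent between genes, so a difference of 1 lay far outside it. That count therefore does not measure false calls in the real data. Of 100 unchanged lists of 20 such independent genes, 6 lay outside the percentile bounds, and 49 of 50 lists shifted by 0.3 lay above the upper one. Alternatives were an intensity-dependent loess centring, an offset of 32 added on the linear scale, the mean of a gene's probe sets, no floor, a floor at the 75th percentile of probe sets (8.86) and a 1.5-fold rule. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.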

Results

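TR1 cells of the small intestine were profiled on 1 array per genotype, to ask which transcripts differ when the cells cannot signal normally through the IL-10 receptor. The 2 samples were the wildtype sample and the impaired sample, whose mice carried a dominant-negative IL-10 receptor under control of the Cd4 gene. Each value below is the log2 RMA expression of a single array, and the differences are impaired minus wildtype. There were no replicates, so no difference could be set against a spread between replicates, and none was tested. Across all 34760 probe sets the arrays correlated with a Pearson r of 0.988 (across probe sets, which are not independent replicates). Of the 11124 genes past the floor, 10940 (98.35%) differed by less than 2-fold, and the middle 95% of the differences lay between -0.51 and 0.85.

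Il10ra, which encodes the ligand-binding chain of the IL-10 receptor, was 5.20-fold brighter in the impaired sample, at 12.30 against 9.92 in the wildtype sample. Its log2 difference of 2.38 was the third highest of all named genes past the floor. Il10rb, the shared second chain of the receptor, stood at 10.30 and 10.13, a difference of 0.16. The single probe set of Il10ra gives 1 value for the whole gene, and whether it detects the transgene is not known without the probe and transgene sequences, so the brighter signal could not be assigned to the transgene or to the endogenous gene. Receptor function was not measured by the array.

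The other members of the IL-10 receptor and STAT3 list differed by less than 2-fold, and more of them were brighter than dimmer in the impaired sample. Socs3, a feedback inhibitor induced by STAT3, was at 9.71 in the impaired and 9.30 in the wildtype sample (difference 0.41). Pim1, a kinase induced by cytokines, differed by 0.34, and Junb, an AP-1 subunit, by 0.27. Among the 17 members past the floor 12 were above 0 and 5 below, and Il10ra alone passed 2-fold. The list's median of 0.16 lay at the 99.94th percentile of matched random lists. Socs3, Pim1 and Junb are also expressed by epithelial cells and neutrophils, whose genes were brighter in the impaired sample (medians 0.86 and 1.69).

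The transcripts by which TR1 cells are recognised were nearly equal in the 2 samples. Il10, the cytokine that defines these cells, was at 12.92 in the impaired and 12.94 in the wildtype sample, a difference of -0.02. Lag3, a co-inhibitory receptor used to identify TR1 cells, differed by -0.05. The largest differences of the TR1 identity list were those of Entpd1, the ectonucleotidase CD39 (0.61), Bhlhe40, a transcription factor that restrains Il10 (0.33), Egr2, a transcription factor of the T cell receptor response (-0.33), and Il21 (-0.31). Chosen after their values were seen, Itga2 (CD49b) differed by 0.10, Maf by -0.02, Prdm1 by -0.20 and Gzmb by -0.15. Of the 24 members past the floor 10 were above 0 and 13 below, and 0 passed 2-fold. The median of -0.01 lay at the 75.11th percentile of matched random lists. How the cells were sorted is not given, so the closeness of these markers may have been set by the sort. It does not show that TR1 identity is independent of the receptor.

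Co-inhibitory receptors showed the same closeness. Ceacam1 (0.69) and Entpd1 (0.61) were brighter in the impaired sample, and Cd244a (-0.39) and Cd160 (-0.39) were dimmer. Chosen after their values were seen, Ctla4 differed by -0.06, Pdcd1 by -0.13 and Havcr2, which encodes TIM-3, by -0.09. Of 17 members 12 were below 0, 0 passed 2-fold, and the median of -0.09 lay at the 13.68th percentile. Ceacam1 is also made by enterocytes, whose genes were brighter in the impaired sample (median 0.86). Among co-stimulatory receptors (median 0.02, 89.06th percentile), Cd81 was brighter by 1.26 and was the only one of 19 past 2-fold. Which cells gave the Cd81 signal was not measured, and enterocyte, B cell and stromal genes were brighter in the same sample (medians 0.86, 0.74 and 0.46). Tnfrsf25 differed by 0.44, Slamf6 by 0.33 and Tnfrsf9 by -0.31.

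**Figure D1:**
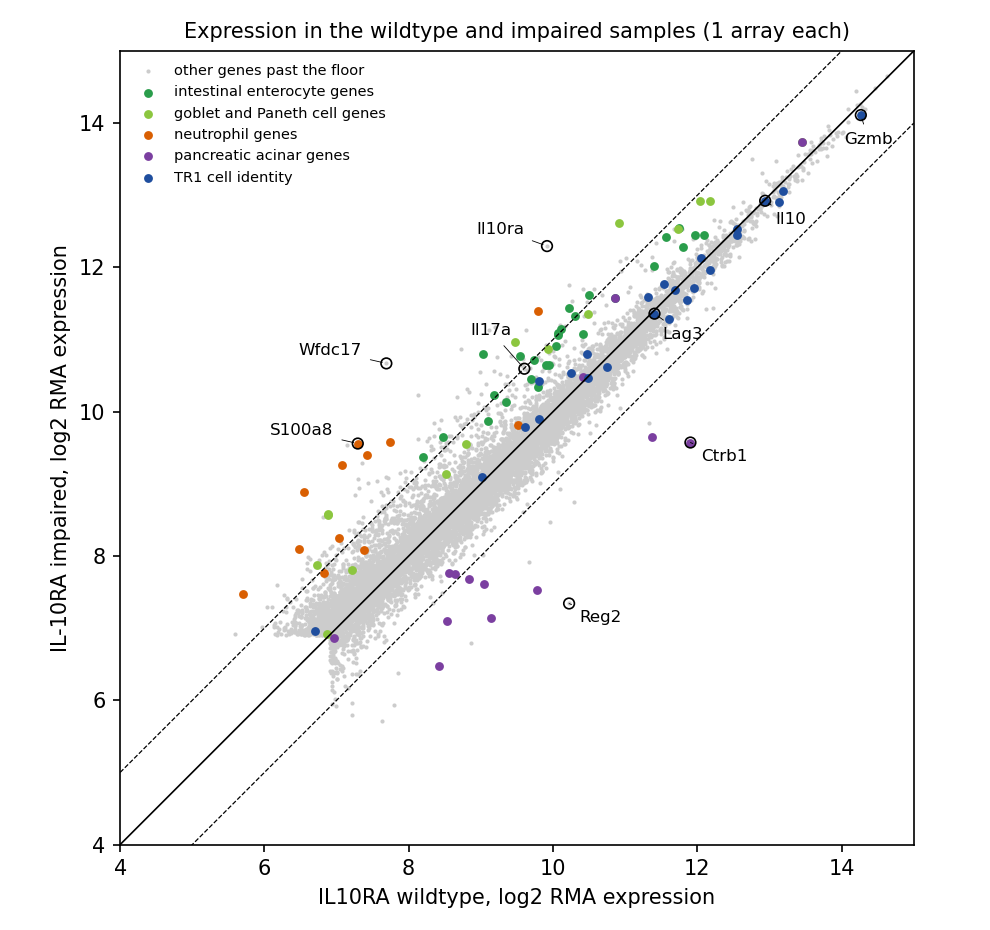
Log2 RMA expression of the 11124 genes past the floor in the wildtype sample (horizontal axis) and the impaired sample (vertical axis), 1 array each, with members of 5 gene lists in colour; the solid line marks equal values and the dashed lines a 2-fold difference. Il10ra lies 2.38 above the line of equality, Il10 (-0.02) and Lag3 (-0.05) lie on it, neutrophil and epithelial genes lie above it, and most pancreatic genes lie below it.

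Cytokine genes differed in both directions. Ifng, the main effector cytokine of TH1 cells, was at 12.29 in the impaired and 12.50 in the wildtype sample (-0.22), and Tnf differed by -0.38. Brighter in the impaired sample were Il2, a T cell growth factor, by 1.08 (7.40 against 6.32), Il17a by 0.99 (10.60 against 9.60), Osm by 0.93 and Ebi3, a subunit of IL-27 and IL-35, by 0.90. Wildtype values of Il2, Osm and Ebi3 lay below the floor of 6.91, so the sizes of their differences are uncertain. Of the 18 members past the floor 11 were above 0, 7 below, and Il2 alone passed 2-fold. The median of 0.13 lay at the 97.64th percentile, just past the bound, and moved inside it after intensity-dependent centring (96.77th) and with a stricter floor (93.44th). Without the 8 members that other cells also express, a choice made after the data were seen, it was 0.23 (99.68th). Neutrophil and epithelial genes were brighter in the same sample.

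Genes of TH17 cells, which make IL-17, had the highest median of the T cell lists when all members were counted. Besides Il17a, its brighter members were Tmem176b (0.88), Ccr6, a chemokine receptor (0.83), and Tmem176a (0.81). Of 16 members 12 were above 0, 8 were at least 1.5-fold brighter and 0 passed 2-fold. Abcb1b, at -0.78, was the lowest member and was chosen after its value was seen. The median of 0.45 lay at the 100th percentile of matched random lists. Without the 9 members that epithelial, myeloid or B cells are also known to express, a choice made after the data were seen, the median of the remaining 7 was 0.29, at the 99.85th percentile, below that of the TH2 list treated alike (0.43). The impaired sample also had brighter B cell genes (median 0.74, and 0.35 when dim probe sets were kept), enterocyte genes (0.86) and neutrophil genes (1.69).

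Genes of the other T helper subsets had lower medians over all members. The TH2 list had a median of 0.25 over 10 members (99.64th percentile), led by Il4 (0.86), Ccr8 (0.51), Pparg (0.44) and Ccr4 (0.43). It lay inside the bounds, at the 92.25th percentile (median 0.11), when dim probe sets were kept. Without the 5 members that other cells also express, the median of the remaining 5 was 0.43 (99.72nd percentile), and all 5 were above 0. The TH1 list had a median of 0.02 over 14 members (81st percentile), with Il12rb1 at 0.29, Cxcr3 at 0.26 and Txk at -0.29. The TFH list had a median of -0.11 over 12 members (7.61st percentile), with Sh2d1a at -0.54, Cd200 at -0.34 and Bcl6, its lineage factor, at -0.34. Foxp3, the lineage factor of regulatory T cells, was at 7.87 and 7.83, and its list had a median of 0.04 over 15 members (76.22nd percentile), with Capg at 0.63, Izumo1r at 0.54 and Il2ra at 0.34. Without a floor the FOXP3 list had a median of 0.13 (97.12th) and the TFH list of -0.03 (37.59th), and with the stricter floor the FOXP3 list had -0.07 (35.64th) and the TH1 list -0.10 (19.61st), all inside the bounds.

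Genes of cytotoxic granules were slightly dimmer in the impaired sample. Serpinb9, which protects cells from granzyme B, differed by -0.36, Fasl by -0.31 and Prf1, which encodes perforin, by -0.28. Klrc1 went the other way, at 0.36. Of 15 members 12 were below 0 and 0 were 1.5-fold lower, and the median of -0.16 lay at the 1.34th percentile of matched random lists. In the same sample epithelial and neutrophil genes were brighter, by medians of 0.86 and 1.69. Cd8a, a marker of CD8 T cells, which also carry cytotoxic granules, was dimmer by 0.70. Trgv1, a gamma-delta T cell receptor gene, differed by -0.40. Cd8b1, another CD8 gene, chosen after its value was seen, differed by -0.09. Of the 7 CD8 and gamma-delta T cell genes past the floor, 4 were below 0 and 3 above. A smaller share of these cells was thus neither shown nor excluded.

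Interferon-stimulated genes were brighter together in the impaired sample, by a small amount. Oasl2 differed by 0.93, Ifitm3 by 0.66, Oas2 by 0.63 and Ifit3 by 0.49. Of 26 members 23 were above 0, 0 passed 2-fold, and the median of 0.21 lay at the 100th percentile. Immediate early genes of the T cell receptor response had a median of 0.11 over 31 members (99.96th percentile), with Dusp4 at 0.80, Atf3 at 0.71, Ier3 at 0.57 and Gadd45g at 0.57. Naive and central memory genes had a median of 0.28 over 14 members (99.94th percentile), led by Igfbp4 (0.74), Klf3 (0.73), Ccr7 (0.46) and Lef1 (0.41); the wildtype value of Igfbp4 lay below the floor. That median became -0.03 with the floor at the 75th percentile of probe sets, and 0.12 over the 4 members that other cells are not known to express, too few for a percentile. Chemokine and homing receptors had a median of 0.11 over 22 members (99.59th percentile), with Ccr6 highest, and lay inside the bounds with the stricter floor (0.025, 92.33rd), after loess centring (0.07, 90.45th) and without the 11 members that other cells also express (0.02, 87.83rd). Among 10 chemokine genes (median 0.23, 99.62nd percentile) Cxcl2, a neutrophil attractant, was brighter by 2.40, Ccl20 by 0.71, Cxcl10 by 0.67 and Cxcl3 by 0.56, and this list too came inside the bounds with that floor (0.10, 95.14th); the 3 members not known from other cells had a median of 0.10. Each of these lists holds genes that epithelial or myeloid cells also express, and the genes of those cells were brighter in the same sample.

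Proliferation and metabolic genes had medians near 0. Of 43 cell cycle genes 20 were above 0 and 23 below (median -0.02, 77.1st percentile), with Cdc6 lowest at -0.46 and Cdca8 highest at 0.28. The p38 and other MAP kinase genes had a median of -0.02 over 26 members (63.09th percentile), although Mapk13, the p38 delta isoform, differed by 0.96. NF-kB genes had a median of 0.01 (84.56th percentile), with Birc2 at -0.37, or -0.18 as the mean of its 2 probe sets. Glycolysis (-0.03, 51.01st), oxidative phosphorylation (-0.04, 61.12nd), cholesterol synthesis (0.05, 83.72nd), apoptosis regulators (0.02, 69.33rd), the unfolded protein response (-0.04, 42.88th) and tissue-resident T cell genes (0.00, 83.63rd) also lay inside the bounds, but the unfolded protein response had a median of -0.21 at the 0.06th percentile with the stricter floor. With that floor the MAP kinase (-0.12, 14.26th), apoptosis (-0.13, 10.45th) and cholesterol synthesis (-0.04, 62.63rd) medians stayed inside. Within these lists Pgam1 differed by 0.49, Ndufa1 by -0.72, Lss by 0.48, Apaf1 by -0.41, Chac1 by 0.73 and Hic1 by -0.31.

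The lists used for RNA quality and for general T cell genes had medians near 0, while olfactory receptor genes, described below, were dimmer in the impaired sample. General T cell genes had a median of -0.03 over 16 members (59.7th percentile), with Thy1 at 0.24 and Cd6 at -0.23. Housekeeping genes had a median of 0.02 (87.36th percentile), ribosomal protein genes of -0.07 (20.55th percentile) and heat shock genes of -0.04 (54.34th percentile). Xist, which is transcribed from the inactive X chromosome, was at 12.83 in the wildtype and 12.76 in the impaired sample, and 0 of the Y-linked genes measured passed the floor.

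Genes of other intestinal cells were among those with the largest differences. All 27 enterocyte genes past the floor were brighter in the impaired sample, with a median of 0.86 (1.82-fold), and 10 passed 2-fold. They were led by Sis, the brush-border enzyme sucrase-isomaltase (1.77), Alpi, intestinal alkaline phosphatase (1.22), Slc5a1, the sodium-glucose cotransporter (1.22), and Lct, lactase (1.19). All 15 goblet and Paneth cell genes were also brighter (median 0.86), with Ang4 at 1.71, Lyz1 at 1.70, Itln1 at 1.68 and Defa24 at 1.497. All 12 neutrophil genes were brighter, with a median of 1.69 (3.23-fold), and 9 passed 2-fold. Mmp8, neutrophil collagenase, differed by 2.35, S100a8 and S100a9, the subunits of calprotectin, by 2.26 and 2.18, and Ngp, a granule protein, by 1.97. Wildtype values of Mmp8, Ang4 and Itln1 lay below the floor, so the sizes of their differences are uncertain, and that of Mmp8 was 2.02 with an offset of 32 added on the linear scale. Each of these 3 lists lay at the 100th percentile of matched random lists. Epithelial genes were bright in the wildtype sample too, with Muc2 at 12.03, Apoa4 at 11.80 and Krt8 at 11.74, chosen after their values were seen. Epithelial signal was thus present in both samples, so T cell genes that epithelial cells share could not be assigned to T cells in either.

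Most pancreatic digestive enzymes went the other way. Ctrb1, chymotrypsinogen, was at 9.57 in the impaired and 11.90 in the wildtype sample (-2.33). The trypsins Try5 and Try10 differed by -2.26 and -1.94, and the carboxypeptidase Cpb1 by -2.00; the impaired value of Try10 lay below the floor. Of 14 members past the floor 11 were below 0 and 8 passed 2-fold, with a median of -1.30 (2.46-fold) at the 0th percentile. Chosen after their values were seen, Clps (colipase) differed by 0.07, Zg16 by 0.30 and Reg1 by 0.71. Zg16 and Reg1 are also members of the epithelial lists. Trypsins, defensins and lysozymes have near-identical paralogs, so the signal of single members is uncertain.

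**Figure D2:**
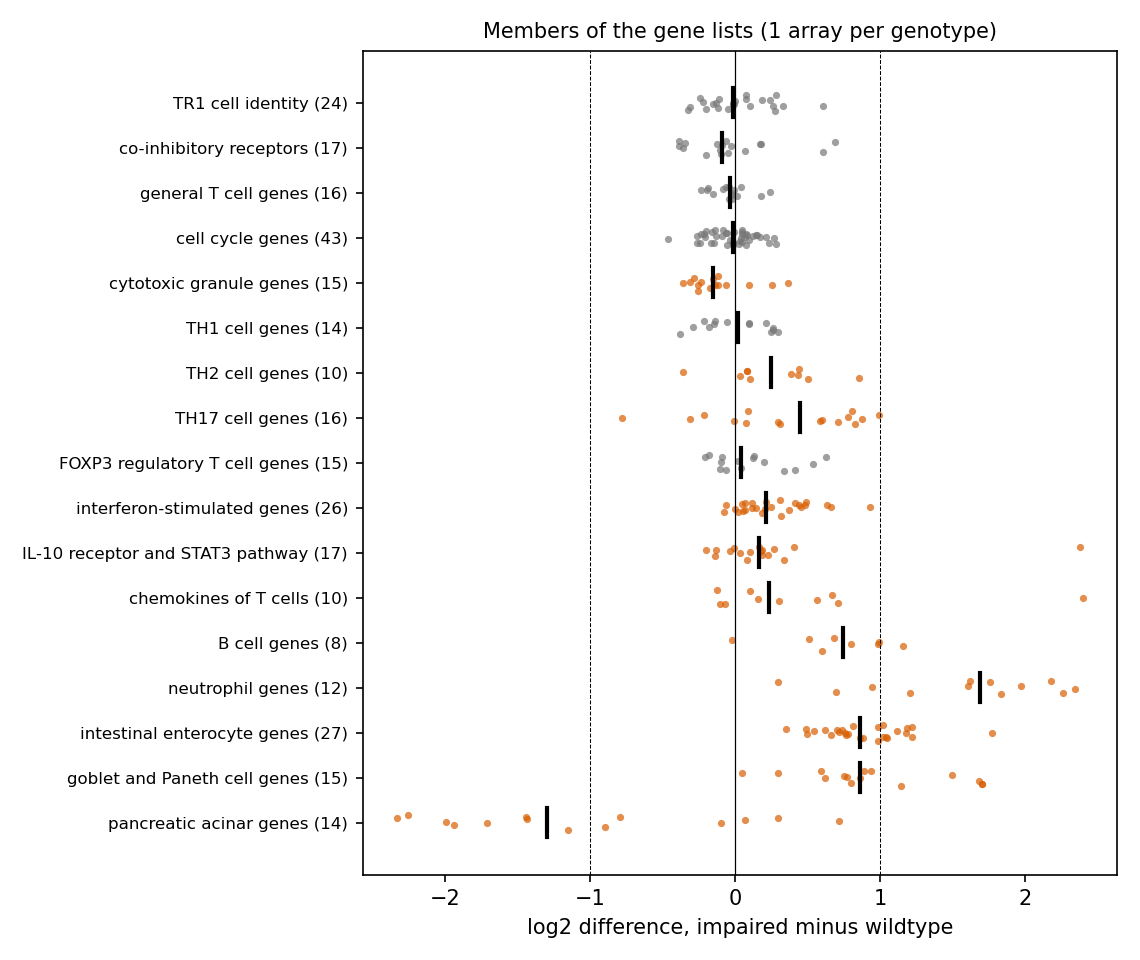
Log2 difference (impaired minus wildtype, horizontal axis) of each member past the floor of 17 gene lists, with the number of members in parentheses; each point is a gene, black bars are medians, and orange marks lists outside the percentile bounds set by matched random lists. TR1 identity and general T cell genes centre near 0, neutrophil genes at 1.69, enterocyte genes at 0.86 and pancreatic genes at -1.30.

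Other cell types gave smaller or mixed values. B cell genes had a median of 0.74 over 8 members (100th percentile), which became 0.35 (also 100th) when dim probe sets were kept, with Cd74 at 1.16, H2-Eb1 at 0.99, Blnk at 0.99 and H2-Ab1 at 0.80. Most of these serve antigen presentation, which dendritic cells and enterocytes also carry out. Stromal and endothelial genes had a median of 0.46 over 10 members (99.89th percentile), with Dcn, decorin, at 1.18 (wildtype value below the floor), and came inside the bounds when dim probe sets were kept (97.44th). Macrophage and monocyte genes had a median of 0.22 over 10 members (97.68th percentile), 8 above 0 and 2 below, with Lyz2 at 1.78 and Tyrobp at 1.03. Lyz1, also in the goblet and Paneth list, was at 1.70. Chosen after their values were seen, Cybb was at -0.55, Ctss at -0.05, Cd68 at 0.09 and C1qa at 0.18. The macrophage list came inside the bounds after loess centring (96.36th), with the offset (97.11th) and with the stricter floor (0.07, 84.72nd). Plasma cell genes (median 0.16, 97.41st percentile) held Ighm at 1.06 and Igha at -0.24, and the 3 probe sets of Ighm all lay above 0. The plasma cell list passed the upper bound after loess centring (98.66th) and with the offset (97.96th). Dendritic cell genes (0.07, 57.88th), natural killer and innate lymphoid cell genes (0.08, 59.49th) and CD8 and gamma-delta T cell genes (-0.09, 21.59th) lay inside the bounds, but with the stricter floor the last list had a median of -0.39 at the 0.06th percentile, outside them. Cd8a itself was at 11.42 in the impaired and 12.12 in the wildtype sample, and Cd8b1, chosen after its value was seen, at 9.72 and 9.80. Trgv1 was at 12.71 in the impaired and 13.11 in the wildtype sample, and Sox13, which went the other way, differed by 0.24. Mast cell, erythrocyte and sex-linked genes had too few members past the floor for a percentile, with medians of 0.24, 0.28 and -0.08.

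Over all genes past the floor, 162 were at least 2-fold brighter in the impaired sample and 22 at least 2-fold dimmer. The highest was Wfdc17, which is made by activated myeloid cells, at 10.67 against 7.69 (2.98). After Cxcl2, Il10ra, Mmp8, S100a8 and S100a9 came Defa39, a Paneth cell defensin (2.15), Muc6, a gland mucin (2.10), Olfm4, a crypt stem cell gene (2.01), Ngp (1.97), Tff2, a trefoil factor (1.97), Gkn3, a gastrokine (1.94), and Retnlg, a neutrophil transcript (1.84). The lowest were Reg2, a pancreatic regenerating protein, at 7.34 against 10.22 (-2.88), Pnliprp1 (-2.08), Gp2 (-1.91), Reg3d (-1.86), Sycn (-1.74), Cpa1 (-1.71), Gkn2 (-1.54), Ctrl (-1.49), Rnase1 (-1.48), AF067061 (-1.47) and Cela3b (-1.44). Impaired values of Pnliprp1, Gp2, Reg3d and AF067061 lay below the floor, so the sizes of their differences are uncertain. Of the 162 genes, 15 were in the epithelial lists, 9 in the neutrophil list and 4 in the lists of T cell programs and pathways. Those 4 were Il10ra, Cxcl2, Cd81 and Il2, and a place in these lists does not show that T cells gave the signal. Of the 22 genes, 8 were in the pancreatic list, 3 were olfactory receptor genes and 0 were in the T cell program and pathway lists, which together held 428 genes past the floor. Beside 162 brighter and 22 dimmer of all 11124 genes, 4 and 0 of 428 do not show that T cell programs were spared. Of the 184 genes past 2-fold, 9 had several probe sets, and in 4 of them these differed in sign.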

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

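Of the 6109 probe sets past the floor that could not be tied to a single gene, and so entered no gene or list comparison above, 53 were at least 2-fold brighter in the impaired sample than in the wildtype sample and 196 at least 2-fold dimmer. They drew attention because they carry a difference outside the named genes, with most of it in the other direction (162 genes brighter and 22 dimmer among named genes). Probe sets shared by several genes gave 13 brighter and 47 dimmer of 889. Probe sets absent from the annotation gave 40 brighter and 149 dimmer of 5220. With 1 array per genotype these counts have no replicate check.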

How the results depend on the processing

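No paired analysis was possible because each genotype had 1 array, and for the same reason no replicate could be left out and no other splits of the samples exist. A value was taken to have moved when it shifted by more than the spread of random list medians (lists) or of single genes (0.253), when a list crossed a percentile bound, or when a count changed by over 1.5 times. These limits were chosen after seeing the data. Il10ra kept its difference within 2.34 to 2.44 under the loess centring, the offset and the mean of probe sets. None of the 175 named genes changed sign from a 2-fold difference, under the same 3 settings, but these could hardly reverse one. The offset cannot change a sign, and the mean leaves genes with 1 probe set, such as Il10ra, as they were. The loess centring moved no named gene by more than 0.253. With the offset, 7 named genes shrank by more than the single-gene spread (AF067061, Dcn, Gp2, Mmp8, Pnliprp1, Reg3d and Try10), each with 1 of its values below the floor. The 162 brighter and 22 dimmer genes became 655 and 167 with the 1.5-fold rule, 107 and 13 with the floor at the 75th percentile, and 165 and 38 without a floor, as a looser rule or a lower floor admits more genes. Leaving out the members of the lists of other cell types, chosen after seeing the data, left 133 and 14. The offset gave 112 and 19, and the mean of probe sets 157 and 21. The loess centring gave 167 and 26, and moved 14 of 40 list medians, among them those of the IL-10 receptor and STAT3 list to 0.226, of the immediate early genes to 0.162, of the TR1 list to 0.039, of the cytokines to 0.14, of the interferon-stimulated genes to 0.26 and of the enterocyte genes to 0.91. The offset brought the neutrophil median to 1.46 and the pancreatic one to -1.15. Without a floor the TH17 median was 0.57, the neutrophil 1.41, the B cell 0.35, the TH2 0.11 and the stromal 0.17. With the stricter floor the cytokine median was 0.083, the neutrophil 1.97 and the pancreatic -1.58, and the naive and central memory median turned from 0.279 to -0.031. Without members that other cells also express, chosen after seeing the data, the medians were 0.23 for the cytokines, 0.29 for TH17, 0.43 for TH2 (0.25 before), 0.17 for the interferon-stimulated genes and 0.02 for the chemokine and homing receptors, of which only the last came inside the bounds. The chemokines (0.23 to 0.10) and the naive and central memory list (0.28 to 0.12) kept too few members for a percentile. The cause of these list shifts was not tested. Of the 17 lists outside the percentile bounds, 10 stayed outside under the loess centring, the offset, the mean of probe sets and both other floors. The other 7 were the TH2, cytokine, chemokine, chemokine receptor, naive and central memory, macrophage and stromal lists. Newly outside were the plasma cell list (0.218 after loess centring, 0.156 with the offset) and, with the stricter floor, the unfolded protein response (-0.207) and the CD8 and gamma-delta T cell list (-0.389), both at the 0.06th percentile. Without detection calls, values near the floor set a limit on folds of dim genes.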

Other observations

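The lists in this part were drawn up after the first results had been seen, but their values were not examined before the tests, except that the tests on the T cell share and on the TH17 list were chosen after the result was seen, and that olfactory receptors were taken up because several had been seen among the lowest genes. Intestinal cell types not described above followed the enterocyte genes. Of 27 further brush-border and junction genes, all were brighter in the impaired sample (median 0.72), with Myo7b at 1.11, Hnf4a, a transcription factor of enterocytes, at 1.02, Ehf at 1.01 and Ezr at 0.07. Enteroendocrine genes had a median of 0.39, and 10 of 11 were above 0. The hormones cholecystokinin (Cck, 1.15), somatostatin (Sst, 0.86) and GIP (Gip, 0.72) were brighter, and proglucagon (Gcg) was at -0.28. The 7 tuft cell genes had a median of 0.47, and Trpm5, their ion channel, was at 0.47 with its wildtype value below the floor. Genes in this paragraph were picked after their values were seen.

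Genes of other cell types set the samples apart. More carried-over epithelial and neutrophil RNA in the impaired sample is a candidate explanation for the brighter genes. Epithelial genes were bright in the wildtype sample too, so the difference would be one of amount. Pooled tuft, enteroendocrine and further brush-border genes (median 0.63, 44 of 45 above 0) lay at the 100th percentile of matched random lists, and 9 further neutrophil genes (median 0.59, all above 0) at the 99.99th. A smaller share of T cells alone would make every other type brighter, and the pancreatic median of -1.30 with 8 of 14 members 2-fold dimmer argues against it. This test was first set on further acinar genes, whose median of -0.14 could not decide it, and was then moved to the pancreatic list, whose median was already known, so it is not an independent test. It concerns only a change of share acting alone. A smaller share of T cells together with less pancreatic RNA was not excluded. The pancreatic list itself was dimmer in the impaired sample. Whether this came from less carried-over pancreatic RNA stays open. Only 3 further acinar genes passed the floor, too few for a percentile, with Pnliprp2 at -0.14, Pla2g1b at -0.28 and Dmbt1 at 0.85. A response of the tissue to the genotype, such as neutrophil entry, also stays open and was not tested, because genotype and sample coincide.

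The TH17 list was brighter in the impaired sample (median 0.45). If this came only from members that epithelial, myeloid or B cells also express, the other 7 should lie inside the bounds, but their median of 0.29 lay at the 99.85th percentile, led by Il17a (0.99) with Il17f and Il23r behind it, both picked after their values were seen. These 7 were tested on the same 2 arrays that showed the pattern, and 3 of them were below 0. Other lymphocytes that make IL-17, a different time of harvest and an effect of the genotype stay open and were not tested.

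Olfactory receptor genes, which T cells are not known to use, were dimmer in the impaired sample: 909 of the 1027 on the array were below 0, with a median of -0.28 taken without a floor. An intensity trend between the arrays is argued against, because the median stayed at -0.28 and at percentile 0.00 of matched random lists after loess centring. Genomic DNA in the wildtype sample may account for it, since a genomic copy of a single-exon gene looks like its transcript. That predicts the same for other single-exon receptor families, and 141 of 151 Vmn1r and Tas2r genes were below 0, with a median of -0.25 at percentile 0.00. Lower amplified RNA yield or higher background in the wildtype sample was not tested. Either might dim these receptor families alike in the impaired sample, so the Vmn1r and Tas2r result does not single out genomic DNA.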
